A study of Homo sapiens with 23 samples.

How the data were processed

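Poly(A)-selected RNA of PC-3 cells was sequenced from 23 libraries, each from 1 well of a 6-well plate, per the labels' protocols. Groups were formed from the clone (I4 or H6), the experiment (N or B) and doxycycline as the labels give them, which made 8 groups with 3 libraries each except 2 for untreated H6 in experiment B. Libraries of experiment N were made with a kit that keeps both strands and those of experiment B with a strand-specific kit, per the labels' protocols. The wells of a group are replicate cultures of a single clone, so the q-values can at most reflect the spread between wells and not between clones. Reads were analysed on hg38, per the submitters' processing notes; the aligner, counting program, annotation release and test are not given in the sources used here.

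The file used here is the authors' own table of 4 comparisons, doxycycline against no doxycycline within each clone and experiment, and it holds no value per library. For each comparison it gives the higher of the 2 group means, a fold change and an adjusted p. The level was made by the authors as the higher group mean on the RPKM scale (reads per kilobase of exon, scaled to the library's reads); the file does not name the unit. It was read from the values, because level times exon length fell on fixed steps in genes of very low level and because the columns sum to 283580 to 301832. The fold change is the authors' own signed ratio, never between -1 and 1, and its direction was read from PARG, which is positive in all 4 comparisons. The q-value is the authors' deposited adjusted p, by a method that is not given in the sources used here. A q-value listed as 0 occurs for 71 to 195 genes per comparison and is printed as such.

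The tests planned before the data were examined were models of counts over all 23 libraries, with contrasts for the average effect of doxycycline, the difference between clones, the difference between experiments and the clones without doxycycline. None of these could be run on a table without values per library. In their place a gene was called changed in a comparison when the authors' deposited q-value was under 0.05, and changed in all 4 when it was called in each with the same sign. Signed folds were put on the log2 scale. The overlap expected of independent lists was the number of genes tested in all 4 times the product of the shares called. Of the 21463 rows, 27 carry names that a spreadsheet turned into dates; these rows entered the counts of calls and are not named.

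Genes are named by a rule fixed before the data were examined, with changes that the file forced: a mean level of at least 1 RPKM stood in for a mean of 1 CPM, and calls in all 4 comparisons with the mean of the 4 log2 folds stood in for the average contrast. The rule takes PARG, the 12 largest rises and the 12 largest falls among genes called in all 4 that have a gene symbol, and the 4 largest rises and falls called in each comparison. It also takes up to 4 members of each gene list called in all 4, ranked by the largest of their 4 q-values, smallest first. Not every list member taken is named below. For the clones without doxycycline it takes the 8 largest differences in each direction with the same sign in both experiments; 1 gene that this last part takes is not reported here. CSF2, LIF, IL6, IL32, PARP1, HSPA5, MT-CYB, MT-ND6, MT-ATP8, MT-ATP6, MT-ND3 and the genes of the closing section outside the lists were chosen after their values were seen.

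The 33 gene lists were fixed before the data were examined, and 30 had at least 3 members of 1 RPKM or more. For each list, calls in all 4 comparisons were set against the other genes of at least 1 RPKM tested in all 4 (10752 in all) with a one-sided Fisher's exact test for more calls, and the 60 tests were adjusted by the Benjamini-Hochberg method. Fisher's exact test treats genes as independent, so its p is too small where members are regulated together, and a test that estimates this correlation needs values per library. For the count adjusted over the list alone, a raw p was bounded from each q-value by its rank among the listed genes, on the assumption that the authors' q-values are Benjamini-Hochberg values. A list's median was also placed among the medians of 10000 random lists of the same size, drawn from 20 bins of level. Such draws treat genes as independent, so a placement is too extreme where members are regulated together. Names were matched to GENCODE v29 on GRCh38 for exon length and position; 21376 of 21463 rows (99.6%) matched, of which 19826 are protein-coding genes.

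Depth was recovered from the level times the merged exon length of genes whose listed mean rests on a single read, a product that is inversely proportional to the number of libraries in the group and to the reads of the library. Between 68.6% and 78.6% of the genes under 1.3 times the lowest step lay within 0.02 of a step, for each comparison. The 22 steps found for 23 libraries gave 33.6 to 43.2 M reads in experiment N and 19.2 to 26.5 M (mega) reads in experiment B, as far as GENCODE v29 lengths are those the authors used.

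The calling and list steps were tested on simulated data with 200 of 10752 genes changed. Of genes changed by a log2 fold of 1, 95.0% were recovered in all 4 simulated comparisons and 96.0% in the simulated comparison of H6 in experiment B; of genes changed by 0.5, 19.0% were recovered in all 4 and 57.0% in the simulated comparison of I4 in experiment N. No unchanged gene was called in all 4, and 15 of 15 simulated lists with planted falls passed. Of 15 lists of unchanged genes 0 passed, which is no check, because without a called gene none could pass. Simulated genes varied independently, so the simulation does not show how the list test behaves where members are regulated together. They were also called by a normal test with their spread known, not by the authors' test on 2 or 3 wells. The recovered shares therefore do not describe the deposited calls. Alternatives were a q-value under 0.01, an absolute log2 fold of at least 1, a level of at least 1 RPKM, and single experiments or clones, planned before the data were examined; a fold of at least 1.5, leaving out each comparison and a level of at least 5 RPKM were added afterwards. The analysis used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.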

Results

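PC-3 is an established human cell line derived from a bone metastasis of prostate cancer. The cells carried a lentiviral construct with the cDNA of PARG, the enzyme that removes poly(ADP-ribose) chains from proteins, fused to the fluorescent protein mClover3 through a cleavable link and placed behind a doxycycline-inducible promoter. From these cells 2 single clones, I4 and H6, were grown for 72 h with or without 500 ng/ml doxycycline, and poly(A)-selected RNA was sequenced. Each clone was examined in 2 independent experiments: experiment N at passage 5, with libraries that keep both strands, and experiment B at passage 7, with strand-specific libraries from another sequencing centre. The 23 libraries formed 8 groups of 3 wells, except the untreated H6 wells of experiment B, which numbered 2. The comparison in each clone and experiment asked which transcripts differ with doxycycline, which induces PARG. Cells without the construct were not analysed here, so effects of doxycycline itself are not separated from those of PARG.

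All values below come from the authors' deposited table, which holds 21463 gene rows and, for each of the 4 comparisons, the higher of the group means on the RPKM scale, a fold change and a q-value. No replicate values were analysed here, so no SD is given. The authors' q-value is the only measure of significance for single genes, and the spread it rests on is not known, because the test is not given. Depth was read from what a single read is worth in genes of very low level, which put the libraries at about 33.6 to 43.2 M reads in experiment N and about 19.2 to 26.5 M (mega) reads in experiment B.

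The table does not state the direction of its folds. PARG, the induced gene, has the same sign in all 4 comparisons and was taken as higher with doxycycline, so its direction is not a result, and every other direction given here rests on it; the sizes of its folds are measured. In the authors' deposited table PARG was 1.35-fold higher in clone I4 in experiment N (q = 9.06e-09) and 1.40-fold higher in experiment B (q = 1.37e-10). In clone H6 the authors' deposited table gives PARG as 2.15-fold higher in experiment N and 1.99-fold higher in experiment B, both with a q listed as 0. The induced PARG level in the authors' deposited table was 29.3 and 37.7 RPKM in I4 and 56.2 and 54.6 RPKM in H6, in experiments N and B respectively. PARG (ENSG00000227345) lies on chromosome 10 from 49818279 to 49970203 on the minus strand of GRCh38. TIMM23B overlaps it on the opposite strand and PARGP1 is a pseudogene copy, so part of its reads can be shared with these, and the endogenous and introduced transcripts were not separated.

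**Figure D1:**
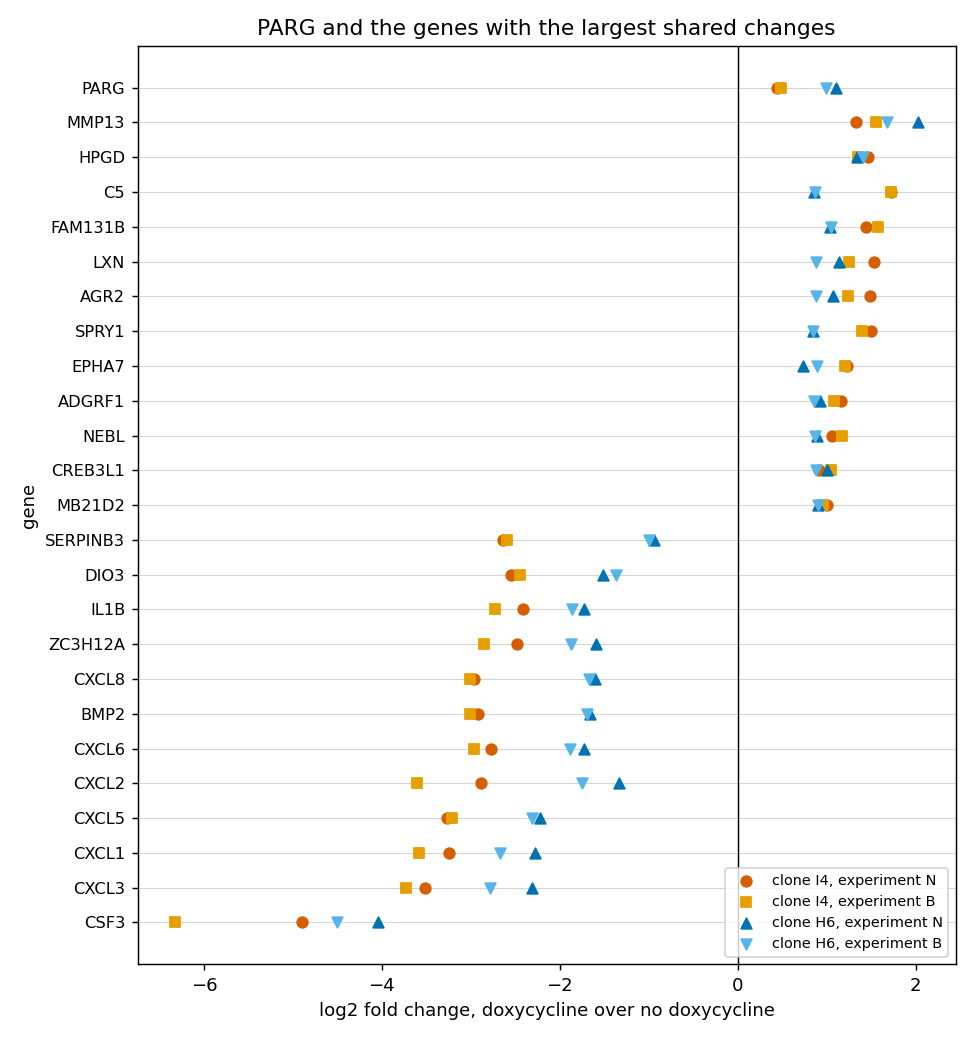
Log2 fold change of doxycycline-treated over untreated cells (x axis) for PARG and for the 12 genes with the largest rises and the 12 with the largest falls shared by all 4 comparisons (y axis), as listed in the authors' deposited table. Each point is 1 comparison, with shape and colour giving the clone and experiment; CSF3 spans -6.33 to -4.05 and PARG 0.44 to 1.11.

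The transcripts that fell most were secreted inflammatory factors, and they fell in both clones. CSF3, which encodes granulocyte colony-stimulating factor, was 16.5-fold to 80.2-fold lower with doxycycline across the 4 comparisons of the authors' deposited table. The 80.2-fold fall, in I4 in experiment B, rests on a level with doxycycline of about 0.08 RPKM, so its size is uncertain. CXCL1, a neutrophil-attracting chemokine at 279.9 to 292 RPKM without doxycycline, was 4.84-fold to 12.01-fold lower in the authors' deposited table. CXCL3, CXCL5, CXCL2, CXCL6 and CXCL8 belong to the same chemokine family, and their falls in the authors' deposited table ranged from 2.52-fold for CXCL2 in clone H6 to 13.3-fold for CXCL3 in clone I4. IL1B, the precursor of the cytokine interleukin-1 beta, was 3.30-fold to 6.61-fold lower, and ZC3H12A, an RNase that degrades inflammatory mRNAs, was 3.01-fold to 7.23-fold lower in the authors' deposited table. The 12 largest falls also included BMP2, DIO3 and SERPINB3, which were 3.16-fold to 8.02-fold, 2.58-fold to 5.86-fold and 1.92-fold to 6.23-fold lower in the authors' deposited table, from levels of at most 4.01 RPKM.

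The largest rises were smaller. MMP13, which encodes a collagenase, was 2.51-fold to 4.09-fold higher with doxycycline in the authors' deposited table, at a level of 1.17 to 1.55 RPKM. HPGD, an enzyme that inactivates prostaglandins, was 2.53-fold to 2.77-fold higher, and the complement component gene C5 1.81-fold to 3.31-fold higher in the authors' deposited table. AGR2, a secreted protein of the disulfide isomerase family, was 1.84-fold to 2.81-fold higher, and LXN, a carboxypeptidase inhibitor, 1.85-fold to 2.89-fold higher in the authors' deposited table. SPRY1, an inhibitor of receptor tyrosine kinase signalling, was 1.79-fold to 2.83-fold higher in the authors' deposited table. The rest of the 12 were FAM131B, the ephrin receptor gene EPHA7, ADGRF1, NEBL, the transcription factor gene CREB3L1 and MB21D2, each between 1.67-fold and 2.98-fold higher in the authors' deposited table.

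Called at a q-value under 0.05, the authors' deposited table lists 2659 changed genes in I4 in experiment N (1215 higher, 1444 lower), 2362 in H6 in experiment N (1138 higher, 1224 lower), 2231 in I4 in experiment B (1184 higher, 1047 lower) and 1203 in H6 in experiment B (578 higher, 625 lower). Most changes were small: the median absolute log2 fold of called genes of at least 1 RPKM lay between 0.31 and 0.38, and a requirement of an absolute log2 fold of at least 1 left 225, 150, 187 and 99 genes in the same order. In all 4 comparisons 562 genes were called, and 556 of them had the same sign, 260 higher and 296 lower. The comparisons share no library, and independent lists of these sizes would share 0.28 genes higher and 0.34 lower among the 15063 genes tested in all 4. Across 10752 genes of at least 1 RPKM, the log2 folds of the clones correlated at Pearson r = 0.71 and Spearman rho = 0.71 in experiment N, and at r = 0.58 and rho = 0.58 in experiment B. Between experiments the correlation was r = 0.72 and rho = 0.65 in I4, and r = 0.56 and rho = 0.69 in H6. These are correlations across genes, which are not independent replicates.

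Of the chemokine and inflammatory cytokine genes, 18 were measured at 1 RPKM or more; 11 fell in all 4 comparisons, none rose in all 4, and 7 were not called throughout. Adjusted over the list alone, 11 fell. Fisher's exact test found more falls in the list than in the other genes (adjusted p = 6.07e-12). Besides those above, the members that fell were CSF2, LIF and IL6. CXCL1, CXCL2, CXCL3, CXCL5, CXCL6 and CXCL8 lie close together on chromosome 4, and Fisher's exact test counts each as a separate gene. The members with mixed values included IL32, which was 2.29-fold and 2.18-fold lower in I4 and 1.14-fold and 1.21-fold higher in H6 in experiments N and B of the authors' deposited table.

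Some genes that respond to the transcription factor NF-kB fell as well. Of 18 members measured, 8 fell in all 4 comparisons and none rose (Fisher's exact test, adjusted p = 2.30e-07); adjusted over the list alone, 9 fell. NFKBIZ was 2.26-fold to 4.39-fold lower, and TNFAIP3, an enzyme that terminates NF-kB signalling, was 1.62-fold to 3.31-fold lower in the authors' deposited table. IER3 and TNIP1 were 1.63-fold to 2.22-fold and 1.49-fold to 1.97-fold lower in the authors' deposited table. In clone I4 all 18 members were called lower in both experiments, and in clone H6 9 were called lower in experiment N and 8 in experiment B. The median log2 fold of the list was -0.81 and -0.89 in I4 and -0.21 and -0.26 in H6, in experiments N and B respectively.

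**Figure D2:**
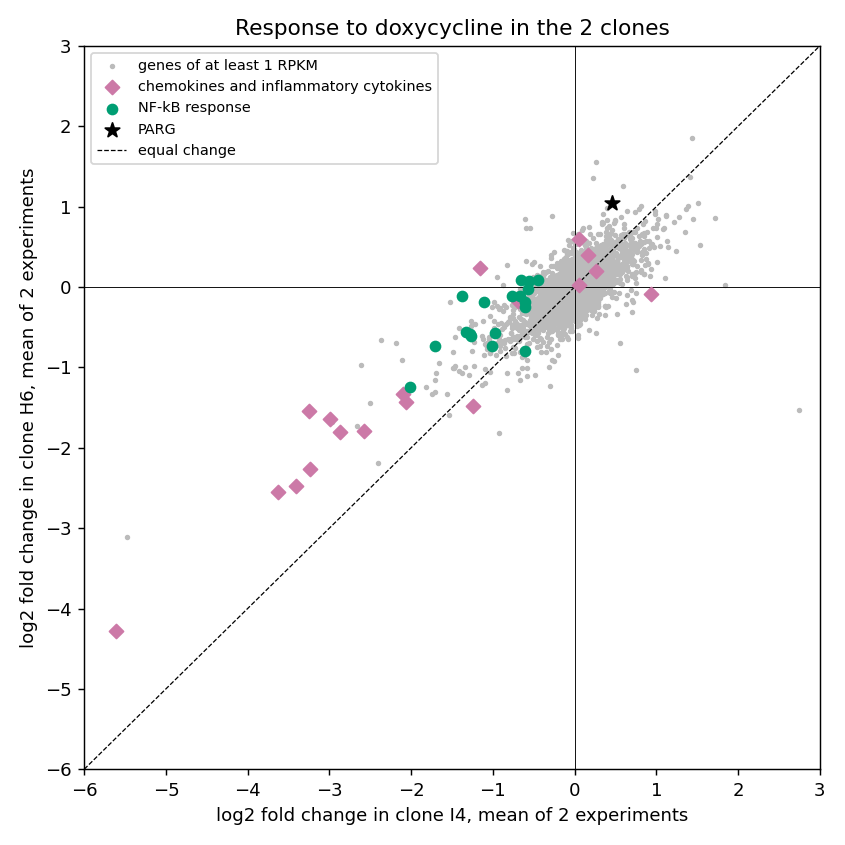
Log2 fold change with doxycycline in clone I4 (x axis) against clone H6 (y axis), each the mean of experiments N and B in the authors' deposited table, for genes of at least 1 RPKM; 2 genes lie outside the axes. Diamonds are chemokine and cytokine genes, circles NF-kB response genes, the star PARG and the dashed line equal change: of the 18 NF-kB genes, 17 fell more in I4 than in H6 in both experiments, and PARG rose more in H6.

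Parts of the lists of angiogenic and vascular factors and of TGF-beta and YAP responsive genes fell. Of 22 angiogenic and vascular factors measured, 6 fell in all 4 comparisons and 2 rose, also when adjusted over the list alone (Fisher's exact test for falls, adjusted p = 0.000172). PLAU, the urokinase plasminogen activator, was 1.81-fold to 2.60-fold lower, and VEGFA, the main vascular growth factor, 1.45-fold to 1.85-fold lower in the authors' deposited table. HBEGF was 1.49-fold to 1.78-fold and NRP2 1.53-fold to 1.66-fold lower in the authors' deposited table. Of 21 TGF-beta and YAP responsive genes, 6 fell in all 4 and 2 rose (Fisher's exact test for falls, adjusted p = 0.000153); adjusted over the list alone, 7 fell and 2 rose. INHBA, TGM2 and IGFBP3 were 2.39-fold to 3.22-fold, 2.06-fold to 2.69-fold and 1.71-fold to 2.98-fold lower in the authors' deposited table. Of 17 mesenchymal genes 2 fell in all 4, TGFBI by 1.85-fold to 3.03-fold and SNAI2 by 1.54-fold to 1.75-fold in the authors' deposited table (Fisher's exact test, adjusted p = 0.293; 2 when adjusted over the list alone). Of 5 metallothionein and zinc export genes 2 fell, MT2A by 1.54-fold to 2.32-fold and MT1X by 1.51-fold to 1.99-fold in the authors' deposited table (Fisher's exact test, adjusted p = 0.0398; 2 when adjusted over the list alone). The metallothionein call was lost within either experiment or either clone alone (Fisher's exact test, adjusted p = 0.0595 to 0.232 there, and 0.0226 at a q-value under 0.01).

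Among the lists that rose, the glycolysis and hypoxia list had the most members called. Of 32 measured, 8 rose in all 4 comparisons and 1, BHLHE40, fell, also when adjusted over the list alone (Fisher's exact test for rises, adjusted p = 8.24e-06). NDRG1 was 1.38-fold to 1.47-fold, P4HA1, a collagen prolyl hydroxylase, 1.21-fold to 1.35-fold and BNIP3, a mitophagy receptor, 1.24-fold to 1.44-fold higher in the authors' deposited table. Of 24 NRF2 target genes 4 rose and 1 fell, also when adjusted over the list alone (Fisher's exact test for rises, adjusted p = 0.0144). ME1 and SLC7A11 were 1.31-fold to 1.53-fold and 1.28-fold to 1.59-fold higher, and AKR1C1 1.49-fold to 2.21-fold lower in the authors' deposited table. Of 19 epithelial genes 3 rose and 1 fell, also when adjusted over the list alone (Fisher's exact test for rises, adjusted p = 0.0466). The keratin genes KRT8 and KRT18 were 1.28-fold to 1.33-fold and 1.20-fold to 1.31-fold higher, DSC2 1.26-fold to 1.59-fold higher and KRT7 1.22-fold to 1.69-fold lower in the authors' deposited table. Of 15 Wnt pathway genes 3 rose and 2 fell, also when adjusted over the list alone (Fisher's exact test for rises, adjusted p = 0.0286), while the median and mean of the list were -0.06 and -0.02. DKK1, a secreted Wnt antagonist at 436 to 992 RPKM, was 1.57-fold to 1.78-fold higher, and the receptor gene FZD8 1.70-fold to 2.17-fold lower in the authors' deposited table. These calls depended on the setting: of 6 alternatives, the NRF2 list kept its call in 3, the epithelial list in 2 (H6 alone and a q-value under 0.01) and the Wnt list in 1 (H6 alone). Over the alternatives, the adjusted p of Fisher's exact test ranged from 0.00947 to 0.248 for NRF2, 0.00338 to 0.274 for epithelial and 0.00987 to 0.257 for Wnt genes.

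Some genes of ribosome production and of entry into S phase fell, while most were not called in all 4 comparisons. Of 33 ribosome biogenesis and nucleolar genes, 8 fell in all 4 comparisons and none rose (Fisher's exact test, adjusted p = 2.59e-05); adjusted over the list alone, 11 fell. MYC was 1.20-fold to 1.40-fold, ODC1 1.28-fold to 1.31-fold and POLR1A, the large subunit of RNA polymerase I, 1.18-fold to 1.37-fold lower in the authors' deposited table. Of 41 G1/S phase genes 7 fell and none rose (Fisher's exact test, adjusted p = 0.00076); adjusted over the list alone, 10 fell. UHRF1, MCM10 and CLSPN were 1.27-fold to 1.36-fold, 1.23-fold to 1.35-fold and 1.25-fold to 1.59-fold lower in the authors' deposited table. Of 41 DNA repair and replication stress genes, only CLSPN fell in all 4 (Fisher's exact test, adjusted p = 1.00; 2 when adjusted over the list alone). In experiment N alone this list passed the test for falls (Fisher's exact test, adjusted p = 0.00178; range over its alternatives 0.00178 to 1.00): 15 members were called lower in each clone there, against 6 in I4 and 4 in H6 in experiment B. Its median of the mean log2 folds, -0.14, was lower than in all 10000 random lists matched on level. The 47 G2/M phase genes had none called in all 4, and their median log2 fold was 0.07 in each comparison. The median of their mean log2 folds lay at percentile 99.6 of random lists matched on level. This placement and that of the DNA repair list treat members as independent genes, so they are too extreme where members are regulated together.

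Other lists had few or no members called in all 4 comparisons, and none passed Fisher's exact test at the main setting. Such counts do not exclude a small shift of a whole list. Among random lists matched on level, the median lay at percentile 99.99 for nuclear-encoded oxidative phosphorylation genes and 99.83 for cytosolic ribosomal proteins. Interferon-stimulated genes lay at 99.85, heat shock genes at 0.29 and mitochondrially encoded subunits at 0. The rest of these lists lay between 0.8 (endothelial markers) and 95.3 (ADP-ribosylation). These placements treat members as independent genes, so they are too extreme where members are regulated together. The rise of the oxidative phosphorylation list lay in experiment N. Its medians were 0.16 in I4 and 0.09 in H6 there, against -0.005 and -0.02 in experiment B. Of 27 interferon-stimulated genes 3 rose and 1 fell (Fisher's exact test for rises, adjusted p = 0.113; the same counts adjusted over the list alone). IFIT2, SAMD9L and IFIT1 were 1.40-fold to 1.58-fold, 1.66-fold to 2.13-fold and 1.42-fold to 1.84-fold higher, and TAP1 1.25-fold to 1.68-fold lower in the authors' deposited table. Of 12 androgen receptor and prostate luminal genes 2 rose and 1 fell, HOXB13 being 1.40-fold to 1.84-fold higher in the authors' deposited table. Of 37 genes of the ATF4 and integrated stress response, SLC7A11 rose and CEBPB fell, and 2 rose when adjusted over the list alone. One member rose in each of the lists of 24 cholesterol synthesis genes (TM7SF2), 20 p53 target genes (CCNG1), 76 mitochondrial ribosomal proteins (MRPS6) and 4 neuroendocrine markers (ENO2), and ROBO4 fell among 4 endothelial markers, of which 2 fell when adjusted over the list alone. No member was called in all 4 among 24 ADP-ribosylation enzymes and readers, 16 NAD metabolism genes, 21 unfolded protein response genes, 20 heat shock genes, 14 histone genes, 75 nuclear-encoded oxidative phosphorylation subunits, 78 cytosolic ribosomal proteins and 13 mitochondrially encoded subunits. PARP1, the main writer of the chains that PARG removes, was lower by 1.38-fold and 1.29-fold in I4 and by 1.25-fold in H6 in experiment N, and 1.16-fold lower with q = 0.0755 in H6 in experiment B of the authors' deposited table. Only 2 fibroblast markers and 2 blood cell markers reached 1 RPKM, none called in all 4, and no nuclear long noncoding RNA of the list has a row.

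**Figure D3:**
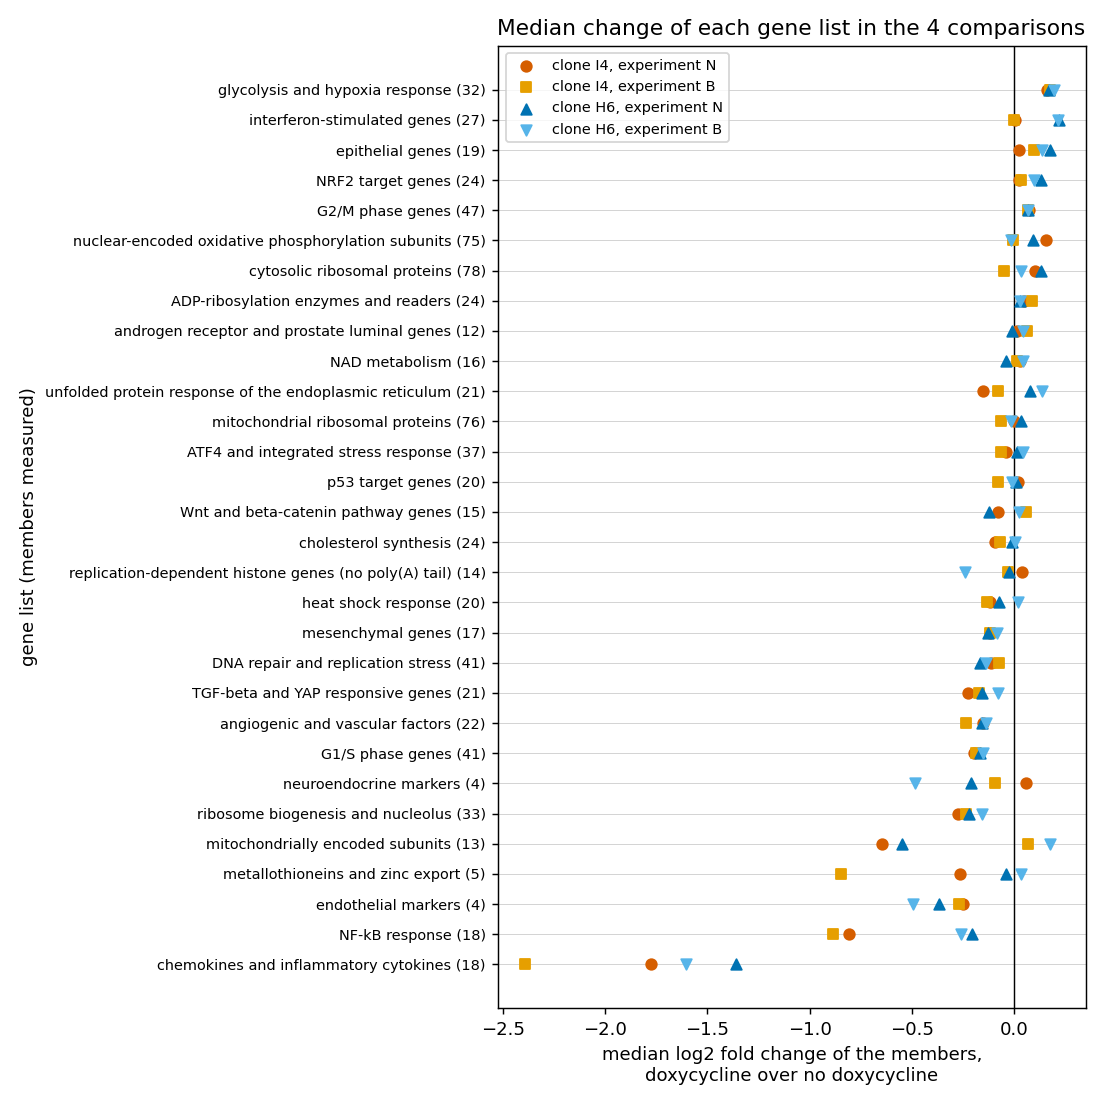
Median log2 fold change with doxycycline over the members of each gene list (x axis) for the 30 lists with at least 3 members of 1 RPKM or more (y axis, number of members in brackets), computed from the authors' deposited table. Each point is 1 comparison; the chemokine list lies between -2.39 and -1.36, and the mitochondrially encoded list lies below -0.5 in experiment N and above 0 in experiment B.

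Within single comparisons, the 4 largest falls of genes of at least 1 RPKM included CSF3 and CXCL3 each time. CXCL5 was among them in I4 in experiment N and in H6 in experiment B, CXCL2 in I4 in experiment B and CXCL1 in H6 in experiment B. The largest rises in I4 included C5, LXN and FAM131B, together with CCL26, a chemokine gene 3.28-fold higher in experiment N (q = 0.014) and 1.12-fold higher in experiment B (q = 1.00) of the authors' deposited table. CLIC3 was 4.03-fold higher in I4 in experiment B, at a level of 0.445 RPKM with doxycycline in the authors' deposited table. In H6 they included MMP13, HPGD and GDF15, a stress-induced cytokine that was 2.46-fold and 2.65-fold higher in H6 and 1.31-fold and 1.04-fold higher in I4, in experiments N and B of the authors' deposited table. TM7SF2, a sterol reductase, was 2.44-fold and 2.36-fold higher in H6 and 1.45-fold and 1.57-fold higher in I4 in the authors' deposited table. The same rule also picked ARL2-SNX15, FAM47E-STBD1, BIVM-ERCC5, HIST2H2AA3 and HIST2H4B. These are read-through genes or near-identical histone copies that share reads with their neighbours, their folds differed widely between comparisons, and they are uncertain.

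The clones differed in the size of the response. Among 529 genes of at least 1 RPKM called with the same sign in all 4 comparisons, the median absolute log2 fold was 0.54 in I4 and 0.46 in H6 in experiment N, and 0.52 and 0.45 in experiment B; 67.9% and 64.1% of these genes had the larger fold in I4. The chemokine and cytokine list had a median log2 fold of -1.78 and -2.39 in I4 and of -1.36 and -1.60 in H6, in experiments N and B respectively; 14 and 16 of its 18 members had the lower fold in I4, with a median difference, I4 minus H6, of -0.78 and -0.88. The interferon-stimulated list had a median log2 fold of 0.01 and -0.003 in I4 and of 0.22 and 0.21 in H6, in experiments N and B respectively. The unfolded protein response list had medians of -0.16 and -0.08 in I4 and 0.07 and 0.13 in H6; HSPA5, the chaperone BiP, had log2 folds of -0.16 and -0.10 in I4 and 0.33 and 0.38 in H6 in the authors' deposited table. For each of these lists the median difference between the clones was lower than in all 10000 random lists matched on level in either experiment, which describes these values and is no test across wells. Without values per well, the difference between the clones could not be tested gene by gene.

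The experiments differed for mitochondrial transcripts. In experiment N 12 of 13 mitochondrially encoded transcripts were called lower in I4 and 5 in H6, with medians of -0.65 and -0.55; in experiment B none was called lower, and the medians were 0.07 and 0.17. Called higher in experiment B were 2 in I4, MT-ATP8 (1.46-fold, q = 1.96e-11) and MT-ATP6 (1.14-fold, q = 0.0411), and 1 in H6, MT-ND3 (1.33-fold, q = 3.18e-06), in the authors' deposited table. Of 75 nuclear-encoded oxidative phosphorylation genes, 22 were called higher and 1 lower in I4 in experiment N, and 20 higher and 2 lower in H6, so most were not called; in experiment B, 2 were called lower in I4 and 1 higher in H6. The medians of this list were 0.16 in I4 and 0.09 in H6 in experiment N, against -0.005 and -0.02 in experiment B. Cytosolic ribosomal protein genes had medians of 0.10 and 0.13 in experiment N, and of -0.05 and 0.03 in experiment B. MT-CYB, which encodes cytochrome b, was 1.59-fold and 1.54-fold lower in experiment N and 1.05-fold and 1.08-fold higher in experiment B, in I4 and H6 of the authors' deposited table. For the mitochondrially encoded list the median difference between experiments, B minus N, was higher than in all 10000 random lists matched on level in either clone, which describes these values and is no test across wells. The 2 experiments differ in passage, sequencing centre and library kit at once, so these cannot be told apart.

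Without doxycycline the clones had different levels of some genes. Uninduced levels are listed in the authors' deposited table for genes that fell and were obtained as the level divided by the fold for genes that rose; the difference has no replicate check here. In both experiments 142 genes differed by at least 2-fold, 98 higher in H6 and 44 higher in I4, and the log2 ratios of the experiments correlated across 10752 genes at r = 0.82 and rho = 0.80. Higher in H6 were SAA1, an acute-phase protein (15.9-fold and 45.8-fold in experiments N and B), RTN4RL2, TENM2, CREB3L1, C1S, CALHM2 and IL1B (5.97-fold and 6.19-fold). Higher in I4 were SHH, the ligand of hedgehog signalling (35.05-fold and 24.4-fold), COX7B2, ONECUT3, LSR, ZNF439, PTPRU and BMP2 (4.46-fold and 5.74-fold), with the uncertain ARL2-SNX15. Some of these ratios rest on very low levels in the lower clone, so their sizes are uncertain. In experiments N and B, SAA1 was at 0.20 and 0.06 RPKM in I4, and SHH at 0.21 and 0.19 RPKM in H6. IL1B in I4 was at 36.3 and 55.3 RPKM.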

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

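The tests of PARG induction, of a generally weaker H6 response, of strand and of the experiments, and the weighing of doxycycline itself, were chosen after the results they bear on had been seen; those of uninduced level and of transcript length were chosen before their values were seen.

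Called in all 4 comparisons of the authors' deposited table, 6 genes changed in opposite directions in the clones, with the same direction in both experiments of a clone. The values are the mean log2 fold in I4 minus that in H6, and these differences were not tested, as no values per well were analysed here. Higher with doxycycline in I4 and lower in H6 were RASL11A (0.83), AL121722.1 (1.01) and the protease gene PRSS23 (0.52). Lower in I4 and higher in H6 were INAVA (-0.81), the interleukin-7 receptor gene IL7R (-0.92) and the kinase gene SGK1 (-0.68). IL7R, for example, was 1.503-fold and 1.516-fold lower in I4 and 1.23-fold and 1.28-fold higher in H6 in the authors' deposited table.

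NF-kB response genes fell more in clone I4 than in clone H6, although PARG rose less there. Had the size of PARG induction alone set the fall, the list would have fallen at least as much in H6. Values seen before the test go against this: the median difference, I4 minus H6, was -0.64 over the 18 members. This difference is the flagged pattern itself, so it is no separate test. In each experiment it lay below all 10000 random lists matched on level. Those lists were not matched on the size of the fall, so this placement adds no support where I4 responds more in general. A generally weaker response of H6 is not decided by these values. The list was flagged for its smaller fall in H6, and the placement below makes no allowance for that choice. The members' median ratio of the H6 to the I4 log2 fold was 0.36, against 0.64 for random sets. Those sets were matched on the fall in I4 and drawn from the 676 genes that fell in both I4 comparisons. The list lay at percentile 0.07 of them. Both placements treat members as independent genes, so they are too extreme where members are regulated together. They describe clones I4 and H6 only and are no test across wells. A higher uninduced level in I4 stays open. The bounds of 0.1 and 0.3 were set for each experiment, over the 14 members lower in all 4 comparisons, called or not. Their median log2 ratio of I4 over H6 lay between the bounds, at 0.169 in experiment N and 0.104 in experiment B. The mean of these was 0.14, and the value in experiment B was close to the lower bound. A difference between the clones other than the PARG transcript level, such as PARG protein or the site of integration, may underlie the pattern and was not tested.

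Of 13 mitochondrially encoded transcripts, 12 were called lower in I4 and 5 in H6 in experiment N, and none in experiment B. Of 75 nuclear-encoded oxidative phosphorylation genes, 22 in I4 and 20 in H6 were called higher in experiment N, against 0 and 1 in experiment B; the list's rise in experiment N was not tested for enrichment. Unstranded counting in experiment N would touch MT-ND6, the 1 member read from the other strand. Even so, 4 of the other 12 members were called lower in both N comparisons. The fall of MT-ND6 itself stays open to unstranded counting. Its level without doxycycline was 555 RPKM in I4 and 419 RPKM in H6 in experiment N, against 87.7 and 80.7 RPKM in experiment B. MT-ATP8, a member not read from that strand, fell more in the authors' deposited table (4.17-fold against 3.18-fold in I4 and 3.10-fold against 2.66-fold in H6). MT-ATP8 overlaps MT-ATP6 on the same strand, so part of its reads can be shared. MT-ATP6 fell 1.647-fold in I4 and 1.499-fold in H6 there, so the fold of MT-ATP8 is not weighed against unstranded counting. Exon length merged over a gene's annotated transcripts is argued against for the nuclear genes. In experiment N their medians were 0.16 in I4 and 0.09 in H6, against 0.006 and 0.029 for lists matched on level and this length. They lay at percentile 99.9 or above among those lists in both N comparisons. The percentiles treat members as independent genes and are too extreme where members are regulated together. In H6 in experiment B a median of only -0.02 lay at percentile 0.365. The length of the transcripts expressed can differ from the merged exon length and was not matched, so transcript length itself stays open. Passage, sequencing centre and library kit cannot be told apart, since the experiments differ in all 3; the median difference for the mitochondrially encoded list, B minus N, was 0.63.

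Chemokine genes fell with doxycycline in both clones and both experiments, 11 of 18 in all 4 comparisons. Doxycycline itself, independent of PARG, and the induced PARG cannot be told apart, because cells without the construct were not analysed here. This holds for these genes and for every other change with doxycycline given here.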

How the results depend on the processing

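The settings of a fold of at least 1.5, of leaving out a comparison and of 5 RPKM were chosen after seeing the data. An absolute log2 fold of at least 1 left 225 genes in I4 and 150 in H6 in experiment N, 187 in I4 and 99 in H6 in experiment B, and 37 in all 4. A fold of at least 1.5 left 559, 398, 491, 300 and 124 in the same order. A q-value under 0.01 moved the count by more than 1.5 times in H6, to 1545 in experiment N and 769 in experiment B; both of these reductions follow from the stricter threshold. Counts at a level of at least 1 RPKM, and counts in all 4 comparisons when any comparison was left out (612 to 806 against 556), stayed within 1.5 times. Of 11 lists past the threshold, 7 stayed past it under every alternative run, and of 177 list values under alternatives 16 lost the call, 7 gained it and 0 reversed; the cause was not tested. The interferon-stimulated list passed in H6 alone and at a q-value under 0.01 (Fisher's exact test, adjusted p = 0.0135 and 0.0491, range over its alternatives 0.0135 to 1.00). The mitochondrially encoded list passed in experiment N alone (Fisher's exact test, adjusted p = 0.00654, range 0.00654 to 1.00). Endothelial markers passed in experiment B alone and in H6 alone (Fisher's exact test, adjusted p = 0.0446 and 0.0459). Androgen receptor and prostate luminal genes passed at 5 RPKM (Fisher's exact test, adjusted p = 0.0486). No paired analysis was possible because the table holds no values per library. For the same reason another scaling, another count model, other low-count filters, PARG left out of the library size, a pseudocount, an additive design, a fit per clone or experiment and leaving out single libraries, though listed before the data were examined, were not run. Experiment B had the lower depth, about 19.2 to 26.5 M reads against 33.6 to 43.2 M in experiment N, and H6 in it had 2 untreated wells; whether either lowered the number of calls was not tested.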

Other observations

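Other gene families, mostly outside the fixed lists, were chosen after their values were seen and were not tested for enrichment. Of 20 immediate early genes measured at 1 RPKM or more, 11 fell in all 4 comparisons and none rose; JUN, a subunit of the AP-1 transcription factor, was 1.45-fold to 1.62-fold lower and the phosphatase gene DUSP1 1.45-fold to 1.86-fold lower in the authors' deposited table. Of 17 HOX genes, 4 rose in all 4 comparisons and 1, HOXB9, fell, with a median of the mean log2 folds of 0.09. Those that rose were HOXB13 and, of 8 HOXA genes, HOXA13 (1.65-fold to 1.94-fold higher), HOXA10 (1.44-fold to 1.54-fold) and HOXA9 (1.20-fold to 1.39-fold) in the authors' deposited table. Of 8 keratin genes, 2 rose (KRT8 and KRT18) and 2 fell (KRT7 and KRT81). Of 16 integrin genes, 2 rose (ITGB4 and ITGB8) and none fell, with a median of 0.07. FOXA1, a pioneer factor of prostate epithelium, was 1.61-fold to 1.96-fold higher in the authors' deposited table, at 23.6 to 42.6 RPKM with doxycycline.

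Among single genes, CD274, which encodes the immune checkpoint ligand PD-L1, was 1.61-fold to 1.86-fold lower in the authors' deposited table. The cell cycle inhibitor gene CDKN1B was 1.20-fold to 1.36-fold higher and CCNG2, a cyclin gene linked to cell cycle exit, 1.34-fold to 1.48-fold higher in the authors' deposited table.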
